A study of Mus musculus with 4 samples.

How the data were processed

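Messenger RNA was measured by sequencing in striatal tissue of 8-week-old C57BL/6 mice, wild-type or homozygous for a humanised Foxp2 allele (Foxp2hum/hum), collected by laser capture from dorsomedial striatum (DMS) or dorsolateral striatum (DLS). The RNA was isolated with a column kit for small samples, and the libraries were prepared with a protocol adapted to low input, indexed, pooled and sequenced on 3 flow cells of an Illumina GAIIx. The submitters' processing notes name the mm9 build, TopHat 1.4.1, bedtools and DESeq, with no versions for the last 2 tools. The deposited table holds a normalised signal per gene and library, which the authors made by dividing read counts per gene by 1 DESeq size factor per library. Of the values, 100% were whole multiples of 1 step per library within a tolerance of 0.01, so whole reads were recovered by multiplying each value by its library's size factor. All 46 libraries were assigned to groups by the header of the table. Recovered totals, summed over the genes, ran from 16.79 to 41.01 M reads per library (M for mega). Pairs of libraries of the same group differed by more than counting error, with a lowest chi-square per degree of freedom of 9.84, so the libraries were not copies of each other.

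Of the 25259 genes in the table, 25023 were found by Ensembl identifier in GENCODE M1, which gave the positions on mm9 and the genes that overlap. The counting appeared to cover whole gene spans on both strands: in every library, each of the 299 genes that lie in an intron of a host and have a mean of at least 500 reads had no more reads than its host, including 209 on the opposite strand. The mean of Myo3a was 522900, against a sum of 520700 for Gm13339, Gm13340 and Gm13341, which lie in its introns. A gene's value can therefore hold reads of an overlapping gene, and for a named gene the largest such overlap is given where it amounts to at least 10% of the value. A read in an overlap can also count more than once in a library's total, and in the shares taken of that total.

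The 19561 genes with a mean deposited value of at least 10 were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with 4 group means fitted over all 46 libraries. The contrasts were Foxp2hum/hum minus wild-type in each region and averaged over the regions, DMS minus DLS in each genotype, and the interaction of genotype and region. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Foxp2 was also compared between genotypes by a two-sided permutation test. Gene lists, 31 in all, were tested with camera at a preset correlation of 0.01, with adjustment over the lists of each contrast, and again with an estimated correlation and with fry. The contrasts, tests, lists and rule for named genes were fixed before the data were examined. That rule took Foxp2, then the 10 genes with the smallest p in each direction among those that passed and had a mean of at least 50 in the higher group, leaving out symbols that end in Rik, contain -ps, or consist of Gm, LOC, BC, AK, AI, AW or AA and digits (clone symbols of other forms, such as AC124169.1 and AU021034, were kept). Where none passed, it took the 5 genes with the smallest p in each direction. It also took members of the lists that passed, and up to 4 members of each list whose set test passed. Animals were not identified, so no block for animal was fitted. If both regions came from the same animals, the tests that span regions treat their libraries as independent, and their p-values may be too large or too small.

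The procedure was tested on simulated counts drawn with the mean and the estimated dispersion of each gene. Genes with a simulated 2-fold change were recovered in 45 of 50 cases for genotype in DMS and 47 of 50 in DLS. With a 1.5-fold change, 28 of 50 and 24 of 50 were recovered. With a 1.25-fold change, 5 of 50 and 1 of 50 were recovered. Genes were drawn independently of each other and the changes of all sizes were simulated together. Recovery in the real libraries, where genes were correlated, may therefore differ. Alternatives were other pseudocounts, filters and normalisations, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, limma array weights, fits of the compared groups alone and a looser threshold. Added after seeing the data were surrogate variables (sva 3.50.0), marker genes as covariates, leaving out libraries 70 and 72 together, and leaving out each library in turn. The 95% intervals are those of limma and cover the spread between libraries, while the floor for a group at 0 covers counting error only. Sequence matches were searched with BLAST+ 2.17.0, and figures were drawn with matplotlib 3.10.9.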

Results

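Gene expression was compared between wild-type mice and mice homozygous for a humanised allele of Foxp2, a forkhead transcription factor gene linked to speech and language, in both subdivisions of the dorsal striatum. The dorsomedial striatum is tied to goal-directed, declarative forms of learning and the dorsolateral striatum to habits and procedures, and the series concerns the passage from declarative to procedural learning. The 46 libraries comprised 11 from wild-type DMS, 12 from Foxp2hum/hum DMS, 11 from wild-type DLS and 12 from Foxp2hum/hum DLS. The median total over the genes, in M (mega) reads, was 23.83 M in wild-type DMS, 24.36 M in Foxp2hum/hum DMS, 20.43 M in wild-type DLS and 22.85 M in Foxp2hum/hum DLS. Mitochondrially encoded genes took 20.2% ± 4.16 of this total in wild-type DMS (SD, n = 11), 22.4% ± 3.84 in Foxp2hum/hum DMS (n = 12), 22.7% ± 3.61 in wild-type DLS (n = 11) and 24.8% ± 2.86 in Foxp2hum/hum DLS (n = 12). Spreads are between libraries. The labels do not tie libraries to animals, so the number of animals behind each group is not given in the sources used here.

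The first question was whether the humanised allele altered the amount of Foxp2 transcript. It did not detectably do so in either region. Foxp2 (ENSMUSG00000029563, mm9 chromosome 6, 14851349 to 15391977) had a normalised read count of 1337 ± 263 in wild-type DMS (SD, n = 11) and 1332 ± 193 in Foxp2hum/hum DMS (n = 12). In DLS it was 1095 ± 202 in wild-type (n = 11) and 1040 ± 221 in Foxp2hum/hum (n = 12). The log2 difference between genotypes was 0.0085 in DMS (permutation p = 0.936, limma adjusted p = 0.993) and -0.08 in DLS (permutation p = 0.507, limma adjusted p = 0.861). Because the allele alters the protein sequence, the level of the transcript does not show which allele a library carries.

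The next comparison asked how the subdivisions differ in wild-type mice. Cnr1, the cannabinoid CB1 receptor gene (ENSMUSG00000044288, chromosome 4, 34011568 to 34035806), was 7.62-fold lower in DMS, with 1643 ± 425 normalised reads against 12430 ± 2550 in DLS (SD, n = 11 each). Crym, which encodes a thyroid hormone binding protein (ENSMUSG00000030905, chromosome 7, 127329894 to 127345625), was 12.01-fold higher in DMS, at 3280 ± 504 against 283 ± 91.8. Among 19561 tested genes, 3377 differed, 1671 higher and 1706 lower in DMS, and 742 of them by more than 2-fold. The log2 difference was -2.93 ± 0.11 (SE) for Cnr1 and 3.59 ± 0.14 for Crym, each with limma adjusted p = 2.01e-26.

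**Figure D1:**
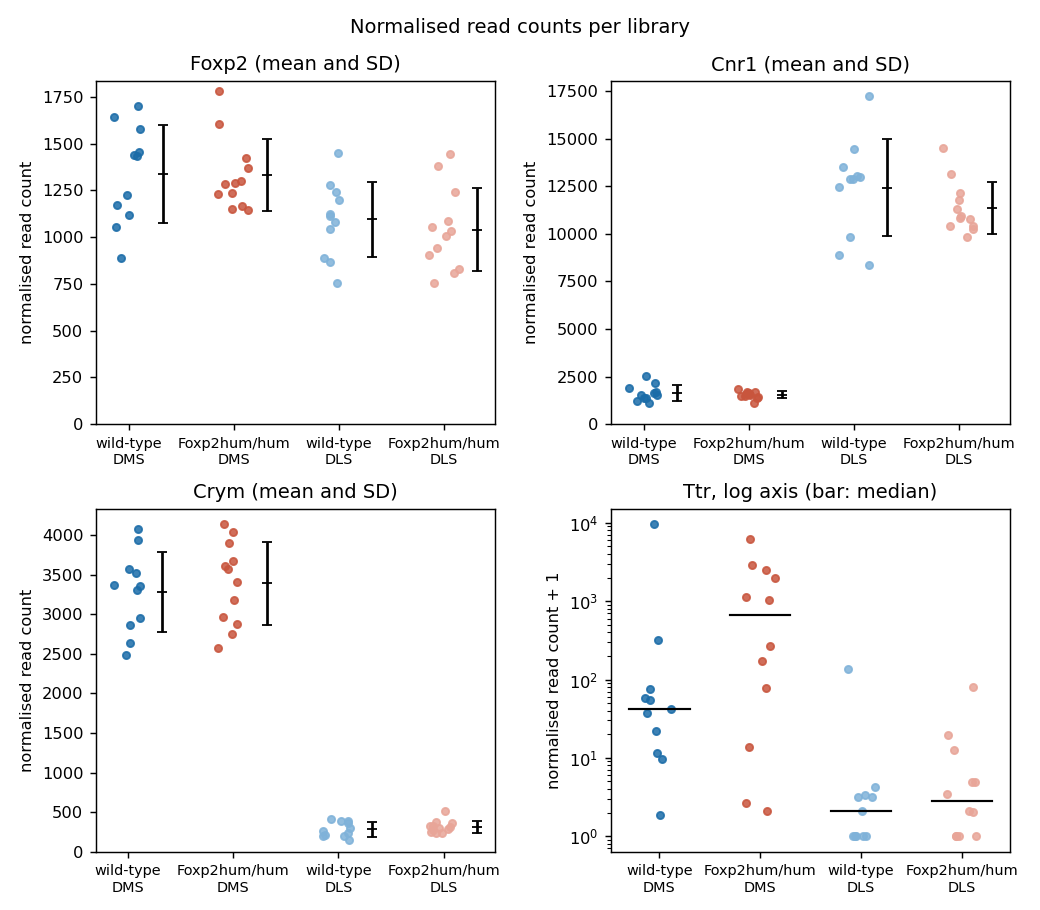
Normalised read counts of Foxp2, Cnr1, Crym and Ttr in each of the 46 libraries (points) by group, with mean and SD bars, or for Ttr a median bar on a log axis of count + 1. Cnr1 averaged 12430 in wild-type DLS and 1643 in wild-type DMS, Crym 283 and 3280, while group means of Foxp2 lay between 1040 and 1337.

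Other genes higher in wild-type DMS by the naming rule were Cpne6, a calcium-dependent membrane-binding protein gene (log2 2.95), Dpp10, which encodes an auxiliary subunit of A-type potassium channels (2.16), Khdrbs2, an RNA-binding protein gene (1.99), Hap1, which encodes a partner of huntingtin (1.35), and Col6a1, a collagen gene (3.56). Blcap (log2 1.92) and Nnat (log2 2.55) were also higher, but Nnat lies within Blcap and held 73.95% of its value, so these 2 genes were not measured separately. Ccdc153, expressed in ciliated cells (log2 6.76), averaged 152 ± 87.6 in DMS and 0.303 ± 0.707 in DLS. AU021034 was at 0 in all 11 wild-type DLS libraries and was at least 252-fold higher in DMS, against a floor of 3 reads over the group. Genes lower in DMS included Nrgn, which encodes the calmodulin-binding neurogranin (log2 -1.90), Rgs4, a regulator of G protein signalling (-1.65), Kcnk2, a two-pore potassium channel gene (-1.19), and Rxrg, a retinoid receptor gene (2.46-fold). Aldh1a1, a retinaldehyde dehydrogenase gene (log2 -2.80), Me2, a mitochondrial malic enzyme gene (-2.26), Kctd17 (-1.52), Cyp2s1 (-2.57) and AC124169.1 (-1.39) were lower too.

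All 3 dorsolateral gradient genes were lower in DMS, and all 3 when adjusted over the list alone: Cnr1, Gpr155 (log2 -1.63) and Coch (-1.33), with camera adjusted p = 1.9e-14 and adjusted p = 4.32e-06 with an estimated correlation. All 6 tested medial and ventral gradient genes were higher, and all 6 when adjusted over the list alone, among them Wfs1 (log2 1.23), Dlk1 (2.10) and Cartpt (1.49), with camera adjusted p = 7.38e-11 and adjusted p = 4.11e-07 with an estimated correlation. Of 16 genes shared by medium spiny neurons, the projection neurons of the striatum, 10 were lower in DMS and 11 when adjusted over the list alone. They included Rasd2 (log2 -0.76) and Ppp1r1b (-0.56), which encodes the dopamine signalling protein DARPP-32 (camera adjusted p = 9.24e-12, adjusted p = 0.0126 with an estimated correlation). The Ppp1r1b value overlaps 1700003D09Rik, which amounts to 78.76% of it. Of 16 potassium and sodium channel genes, 8 were lower and 11 when adjusted over the list alone, for example Kcnab1 (log2 -0.78), Kcnip2 (-0.62) and Scn4b (-0.91), with camera adjusted p = 1.39e-08 and adjusted p = 0.0405 with an estimated correlation. Of 10 choroid plexus and ependyma genes, 7 were higher and 7 when adjusted over the list alone, including Tmem212 (log2 5.78, with SNORA81.2 overlapping at 10.86% of its value), Foxj1 (1.95) and Folr1 (3.29), with camera adjusted p = 3.07e-09 and adjusted p = 0.00146 with an estimated correlation. The choroid plexus gene Ttr had a median of 40.8 normalised reads in wild-type DMS, with a highest library of 9582, against a median of 1.09 in wild-type DLS.

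Another 8 lists passed camera in wild-type but not with an estimated correlation. Of 14 endocannabinoid and long-term depression genes, 6 were lower and 6 when adjusted over the list alone, including Dagla (log2 -1.03), which encodes the enzyme that makes the endocannabinoid 2-arachidonoylglycerol, and Plcb4 (-0.97), with adjusted p = 0.0739 with an estimated correlation. Of 17 immediate early genes, which respond to neuronal activity, 7 were higher and 7 when adjusted over the list alone, among them Fosb (log2 1.41), Egr2 (1.41) and Nr4a3 (1.52), with adjusted p = 0.456 with an estimated correlation. Of 22 neurite outgrowth and guidance genes, 7 were higher and 1 was lower (10 and 1 when adjusted over the list alone), with Dcx (log2 2.69), a marker of immature neurons, Gap43 (0.46) and Robo2 (-0.65), and adjusted p = 0.393 with an estimated correlation. The D2 receptor gene Drd2 (log2 -0.64) and the adenosine receptor gene Adora2a (-0.71) were the 2 of 5 indirect-pathway genes that were lower, and 2 were when adjusted over the list alone, with adjusted p = 0.189 with an estimated correlation. Of 37 mitochondrially encoded genes, 6 were lower and 8 when adjusted over the list alone, mt-Tm by log2 -0.45, with adjusted p = 0.456 with an estimated correlation. Of 76 cytosolic ribosomal protein genes, 5 were higher, Rpl10 by log2 0.41, and 0 when adjusted over the list alone, with adjusted p = 0.568 with an estimated correlation. Of 12 oligodendrocyte genes, 2 were higher, Cldn11 (log2 0.31) and Mal (0.35), and 2 when adjusted over the list alone, with adjusted p = 0.456 with an estimated correlation. Of 23 glutamate receptor genes, 7 were lower (9 lower and 3 higher when adjusted over the list alone), among them Grik2 (log2 -0.45) and Grik5 (-0.40), with adjusted p = 0.555 with an estimated correlation.

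Regional p-values rest on libraries, and adding the levels of Ttr and Ccdc153 as covariates reduced the wild-type count from 3377 to 258, while Ttr alone left 2758. Over the 3377 genes, the median log2 along the direction of the main fit was 0.54 with a median SE of 0.125, and 0.39 with 0.326 when both were added. Fits with surrogate variables gave more genes, up to 5857 with 3 surrogate variables.

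The same comparison in Foxp2hum/hum mice asked whether the regional difference is present with the humanised allele. It was: Cnr1 averaged 1536 ± 183 in DMS and 11370 ± 1347 in DLS (SD, n = 12 each), 7.41-fold lower in DMS, and Crym 3391 ± 521 and 315 ± 77.03, 10.89-fold higher. In these mice 3550 genes differed, 1825 higher and 1725 lower in DMS, 761 of them by more than 2-fold. Limma gave adjusted p = 7.05e-27 for Cnr1 and 1.75e-26 for Crym. Of the 20 genes the rule named, 17 were also named in wild-type. The others were Pdyn, the prodynorphin gene (log2 1.60), Tmem212 (5.72), and Rcn1, a calcium-binding protein gene of the endoplasmic reticulum (-1.34). Foxp2 was higher in DMS in Foxp2hum/hum (log2 0.37 ± 0.11 SE, limma adjusted p = 0.00931). In wild-type its difference was 0.28 ± 0.11 and did not pass (adjusted p = 0.0743), and the interaction was 0.09 ± 0.16 (adjusted p = 1). The wild-type Foxp2 difference passed with quantile normalisation (adjusted p = 0.025), array weights (adjusted p = 0.0153) and each number of surrogate variables (adjusted p = 0.0024 with 1), and the Foxp2hum/hum difference did not pass with Ttr as a covariate (log2 0.24 ± 0.13 SE, adjusted p = 0.278) or with Ttr and Ccdc153 (0.68 ± 0.26, adjusted p = 0.164), where the SE was larger.

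**Figure D2:**
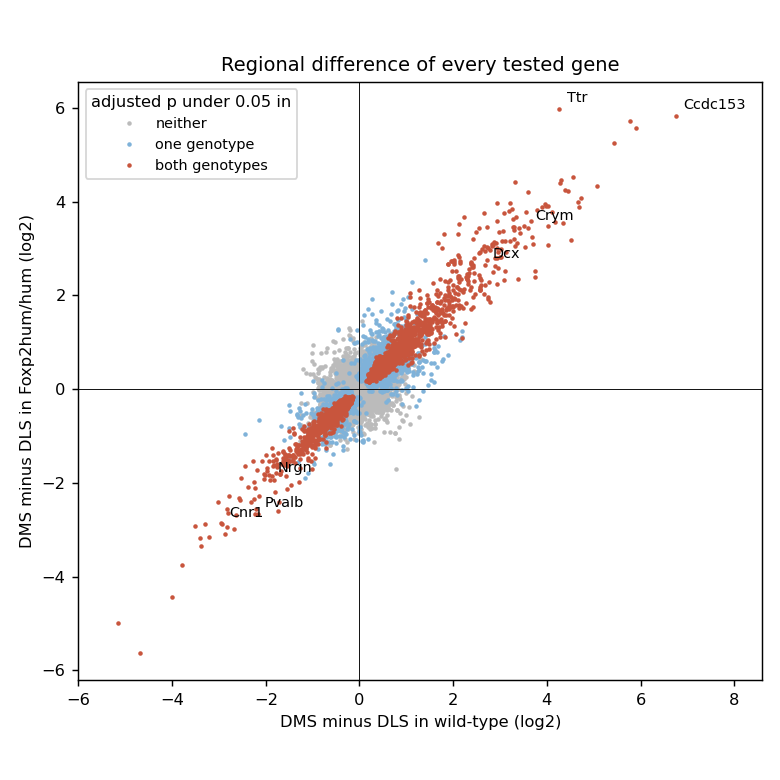
Difference between DMS and DLS of every tested gene in wild-type (horizontal, log2) and Foxp2hum/hum (vertical, log2), with colours for genes that passed in neither, 1 or both genotypes. The 2550 genes called in both genotypes lie in the quadrants of equal sign, for example Cnr1 at -2.93 and -2.89 and Ccdc153 at 6.76 and 5.82.

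In Foxp2hum/hum the 3 dorsolateral gradient genes were lower in DMS (camera adjusted p = 7.51e-14, adjusted p = 6.61e-06 with an estimated correlation) and the 6 medial and ventral gradient genes were higher (camera adjusted p = 3.37e-12, adjusted p = 8.1e-08 with an estimated correlation). Of the 16 shared medium spiny neuron genes 10 were lower (11 when adjusted over the list alone), Ppp1r1b by log2 -0.56 (adjusted p = 0.0144 with an estimated correlation). Of 16 potassium and sodium channel genes 10 were lower (11 when adjusted over the list alone), including Kcnab1 (log2 -0.74) and Hcn2 (-0.70), with adjusted p = 0.0458 with an estimated correlation. Of 10 choroid plexus and ependyma genes 7 were higher (7 when adjusted over the list alone), Ttr by log2 5.98 and Folr1 by 3.46 (adjusted p = 0.000483 with an estimated correlation). Median Ttr was 659 in Foxp2hum/hum DMS and 1.78 in Foxp2hum/hum DLS. Among 11 striatal interneuron genes, Pvalb, the parvalbumin gene (log2 -2.67), and the cholinergic genes Chat (-0.74) and Slc5a7 (-0.75) were lower, and the list passed camera but had adjusted p = 0.218 with an estimated correlation. In wild-type Pvalb was lower by log2 -2.17, Chat by -0.78 and Slc5a7 by -0.76, while Pthlh was higher (0.50), and the list did not pass (camera adjusted p = 0.208). Of 14 endocannabinoid and long-term depression genes 6 were lower and 6 when adjusted over the list alone (adjusted p = 0.0897 with an estimated correlation). Of 17 immediate early genes 7 were higher and 8 when adjusted over the list alone (adjusted p = 0.445 with an estimated correlation). Of 22 neurite genes 8 were higher and 1 was lower, or 10 and 1 when adjusted over the list alone (adjusted p = 0.356 with an estimated correlation). The remaining lists that passed camera had adjusted p = 0.171 (indirect pathway), adjusted p = 0.398 (mitochondrially encoded), adjusted p = 0.68 (ribosomal), adjusted p = 0.614 (glutamate receptor), adjusted p = 0.656 (synaptic) and adjusted p = 0.74 (respiratory chain) with an estimated correlation. With Ttr and Ccdc153 as covariates the count of genes was 348, and with Ttr alone 2279; over the 3550 genes the median log2 went from 0.54 with a median SE of 0.122 to 0.43 with 0.302 when both were added. With 5 surrogate variables it was 6167.

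Comparing the genotypes' regional differences directly, 2550 genes passed in both, all 2550 in the same direction. Of these, 1245 were higher in DMS in both (155.9 by chance) and 1305 were lower (150.4 by chance). Among the 4377 genes called in either genotype, 98.56% had the same sign. Across the 19561 genes, which are not independent replicates, the differences correlated with r = 0.870 (Spearman 0.756). A further 827 genes passed in wild-type alone and 1000 in Foxp2hum/hum alone, but 0 genes had an interaction of genotype and region by limma, edgeR or DESeq2, with 321 at an unadjusted p under 0.05 and 978 by chance. The smallest adjusted p was 1. The 321 ran from 153 (mean of at least 50) to 696 (8 surrogate variables) and stayed under the count by chance. Genes with the smallest interaction p included Siah1b (log2 0.57 ± 0.18 SE), Cmya5 (0.67 ± 0.23), AC138376.2 (0.51 ± 0.17), Ckap2l (1.44 ± 0.51, with Gm14024 overlapping at 12.94%) and Whamm (0.47 ± 0.17). In the other direction were Psg23 (-0.83 ± 0.27), Tacc3 (-1.04 ± 0.34), Tmem173 (-0.75 ± 0.25), AC172623.1 (-0.46 ± 0.15, with Med26 overlapping at 258.1% of its value) and Drd5 (-1.01 ± 0.35). Drd5, a D1-like dopamine receptor gene, was lower in DMS in Foxp2hum/hum (log2 -1.09, adjusted p = 0.000584) and not in wild-type (-0.08, adjusted p = 0.878), but its interaction had adjusted p = 1, and Gm16766 overlaps it with 51.24% of its value.

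In DMS the question was which genes the humanised allele alters in goal-directed striatum. No gene passed. Those with the smallest p were higher in Foxp2hum/hum for Mrpl19, a mitochondrial ribosomal protein gene (350 ± 44.2 to 420 ± 65.1 normalised reads), Snx4 (375 ± 53.3 to 460 ± 68.4), Zfp711 (51 ± 22.2 to 74.8 ± 20.2), Cdkn2aip (139 ± 24.5 to 185 ± 41.7) and Dcaf13 (245 ± 28.3 to 298 ± 45.3; SD, n = 11 wild-type and 12 Foxp2hum/hum). Mrpl19 overlaps AW146020, at 35.01% of its value. Lower values were found for Slc10a7 (97.0 ± 25.6 to 63.4 ± 21.6), Ppp1r3f (453 ± 31.4 to 380 ± 36.5, with Ccdc22 overlapping at 40.44%), and, by the same rule, Lipe, the hormone-sensitive lipase gene (4732471J01Rik overlapping at 12.44%), Pygm, the muscle glycogen phosphorylase gene, and Abtb2. All 10 had limma adjusted p = 0.955. The count was 0 by limma, edgeR and DESeq2, with 700 genes at an unadjusted p under 0.05 and 978 by chance. The 700 depended on single libraries, with 453 without library 72, 989 without 34 and 979 without 50, and it was 461 without 70 and 72. The 95% interval excluded a 1.5-fold difference for 71.66% of the tested genes, and for 88.13% of the 15263 genes with a mean of at least 50.

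Of the 31 lists, 7 passed camera in DMS and 0 with an estimated correlation, and 0 members passed, also when adjusted over the list alone. Ribosomal (median log2 0.13), respiratory chain (0.11) and mitochondrially encoded genes (0.16) were on the higher side, for instance Rpl5 (0.24 ± 0.14 SE, with Fam69a overlapping at 10.4%), Atp5f1 (0.19 ± 0.11, with Wdr77 overlapping at 11.82%) and mt-Tt (0.37 ± 0.15). Oligodendrocyte (median log2 -0.10), endothelial and mural (-0.14), immediate early (-0.30) and synaptic genes (-0.15, with Vamp2 at -0.14 ± 0.07) were on the lower side. All 7 lists had adjusted p = 0.521 with an estimated correlation, and fry called 0 lists. The share of mitochondrially encoded reads was 20.2% in wild-type and 22.4% in Foxp2hum/hum, and Ttr had medians of 40.8 and 659. Leaving out library 34 raised the 7 lists to 15, library 50, 56 or 31 to 12, and library 84 to 11.

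In DLS, the subdivision tied to procedural learning, no gene passed either. Myo3b, an unconventional myosin gene (ENSMUSG00000042064, chromosome 2, 69877183 to 70267255), came closest, with 497 ± 112 normalised reads in wild-type and 331 ± 74.2 in Foxp2hum/hum (SD, n = 11 and 12), a log2 difference of -0.59 ± 0.12 (SE) and limma adjusted p = 0.344. It passed with DESeq2 (adjusted p = 0.0196) and with array weights (adjusted p = 0.012). DESeq2 also called Ccdc153 (log2 3.84) and AI115009 (-1.86), both named after their values were seen, with adjusted p = 0.0196 for each. Ccdc153 was very low in DLS, at 0.303 ± 0.707 normalised reads in wild-type and 5.17 ± 8.13 in Foxp2hum/hum (SD). Its log2 difference therefore rests on values near the floor. With library 77 left out, limma called AI115009 (log2 -1.89, adjusted p = 0.0144). Also on the lower side were Foxo6, a forkhead transcription factor gene (156 ± 15.8 to 117 ± 38.05), Mybbp1a (553 ± 103 to 413 ± 83.5, with Spns2 overlapping at 47.97%), Mak (94.4 ± 13.4 to 65.2 ± 20.6) and AC087117.1, which Vars overlaps with 425% of its value. On the higher side were Vsnl1, which encodes the neuronal calcium sensor visinin-like protein (727 ± 157 to 905 ± 150), Tacc3 (33.8 ± 19.5 to 56.3 ± 20), Tmem38b (68.1 ± 12.7 to 92.1 ± 20.98), Mtrf1l (53.5 ± 14.9 to 74.7 ± 16.2) and Giyd2, which Bola2 overlaps with 289.9% of its value. These 9 had adjusted p = 0.843. The count was 0 by limma and edgeR and 3 by DESeq2, with 843 genes at an unadjusted p under 0.05 and 978 by chance. The 843 was not stable either: it was 1821 without library 51, 1642 without 94, 1354 without 43, 1126 without 74 and 1111 without 83, 1816 with array weights and 521 with Ttr and Ccdc153 as covariates. The 95% interval excluded a 1.5-fold difference for 70.15% of the tested genes.

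Of the lists, 10 passed camera in DLS and 0 with an estimated correlation. Striosome genes, markers of the patch compartment, had a median log2 of -0.17, passed fry (adjusted p = 0.0272), and had adjusted p = 0.119 with an estimated correlation. With 5 surrogate variables, chosen after seeing the data, they had adjusted p = 0.0381 by fry and adjusted p = 0.0313 with an estimated correlation. Their member Pdyn stood at 907 ± 165 in wild-type and 734 ± 99.2 in Foxp2hum/hum, a log2 difference of -0.29 ± 0.09 (SE). Pdyn did not pass over all genes (adjusted p = 0.843) but did when adjusted over the list alone (adjusted p = 0.0132). Adjusted over the list alone, Pdyn also passed in the direct-pathway and neuropeptide lists (adjusted p = 0.0181 in each) and Dlk1 in the medial and ventral gradient list (adjusted p = 0.0107). So did Ccdc153, at values near the floor, in the choroid plexus and ependyma list (adjusted p = 0.0114). Ribosomal (median log2 0.19), respiratory chain (0.15) and mitochondrially encoded genes (0.19) were on the higher side. Shared medium spiny neuron (-0.07), direct-pathway (-0.13), immediate early (-0.28), endocannabinoid (-0.09), synaptic (-0.14) and channel genes (-0.11) were on the lower side. The direct-pathway list had adjusted p = 0.557 and the other 8 lists adjusted p = 0.674 with an estimated correlation. The share of mitochondrially encoded reads was 22.7% in wild-type and 24.8% in Foxp2hum/hum.

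**Figure D3:**
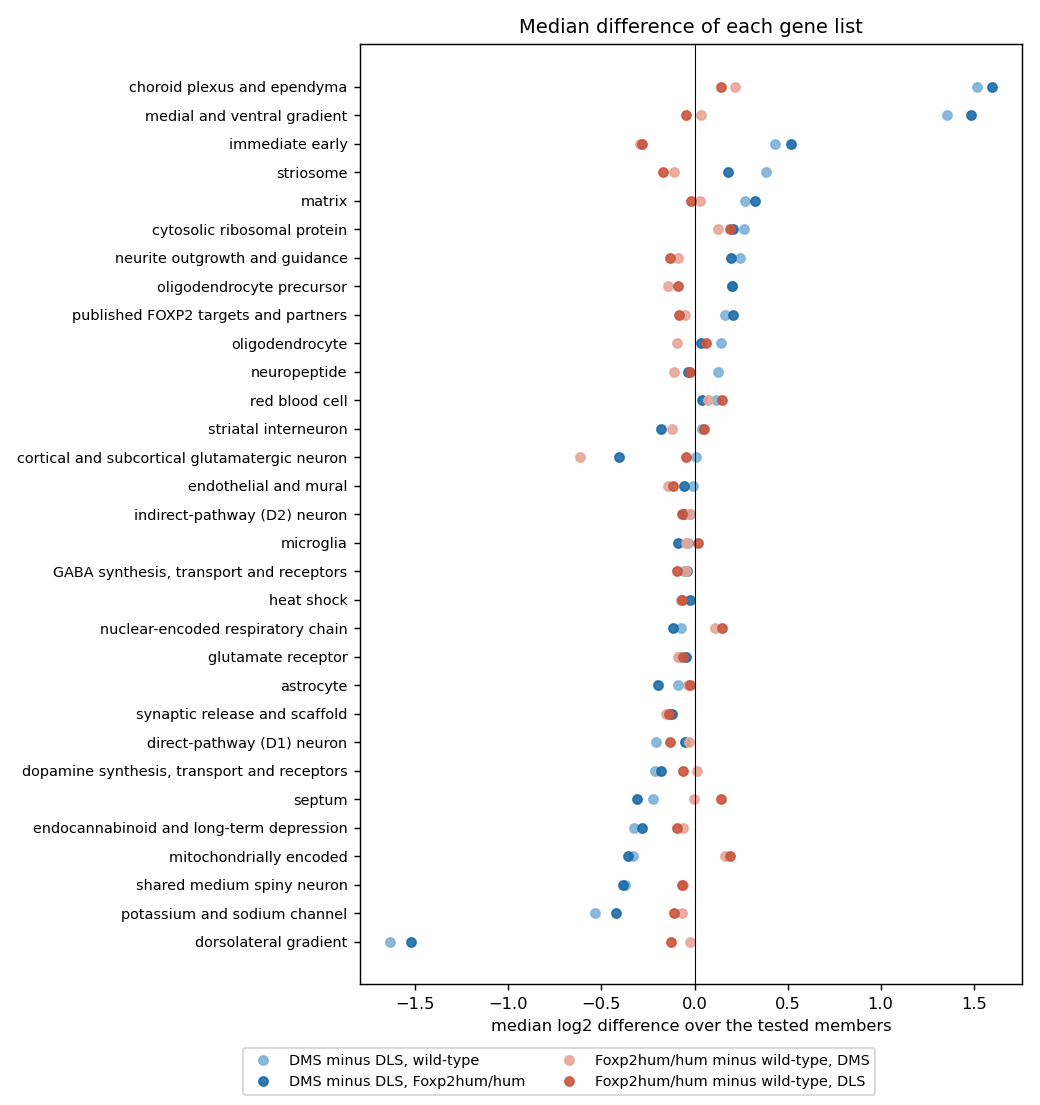
Median log2 difference over the tested members of each of the 31 gene lists, between regions (blue) and between genotypes (red). The regional medians run from -1.63 to 1.60, and the median of the dorsolateral gradient list was -0.03 between genotypes in DMS and -0.13 in DLS.

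Averaged over the regions, the genotypes differed in 0 genes by limma, edgeR and DESeq2, with 1679 at an unadjusted p under 0.05 against 978 by chance and a smallest adjusted p of 0.574. Genes with the smallest p were on the higher side for Vsnl1 (log2 0.27 ± 0.07 SE), Tprkb (0.20 ± 0.05), Ormdl3, a regulator of sphingolipid synthesis (0.18 ± 0.05), Rbmx (0.20 ± 0.05) and Tceal8 (0.34 ± 0.09). On the lower side were Myo3b (-0.35 ± 0.09), Mybbp1a (-0.30 ± 0.08), Foxo6 (-0.32 ± 0.09), Ccdc21 (-0.23 ± 0.07) and AC087117.1 (-0.51 ± 0.12). The striosome list passed fry (adjusted p = 0.00996, adjusted p = 0.155 with an estimated correlation), but not with 5 surrogate variables (adjusted p = 0.0606 by fry, adjusted p = 0.0558 with an estimated correlation). Camera called 13 lists, and 0 with an estimated correlation, where the glutamate receptor list had adjusted p = 0.528 and the other 11 lists adjusted p = 0.477. Sfxn1, adjusted over the list alone, passed in the direct-pathway list (adjusted p = 0.0179), as did Ccdc153 in the choroid plexus and ependyma list (adjusted p = 0.0179). Ccdc153 was very low in both DLS groups. Libraries 70 and 72 hold features far above the other libraries, and without them the count at an unadjusted p under 0.05 was 931. It was 2767 without library 51, 2629 without 94, 1006 and 1067 with 2 and 3 surrogate variables, and 671 with Ttr and Ccdc153 as covariates. The 95% interval excluded a 1.5-fold difference for 84.38% of the tested genes and for 96% of those with a mean of at least 50.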

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

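Of the tests in this part, the splits were set before their results were seen, and the tests with Ttr and Ccdc153, with Ttr alone and of other cell types were chosen only after the result was seen, the one with Ttr alone after the fit with both markers had reduced the calls, though before its own value. The oligodendrocyte list was singled out because its genotype difference was not the same in the 2 regions by a test of the interaction itself (camera adjusted p = 0.00145, median log2 -0.12, 12 genes). With an estimated correlation it had adjusted p = 0.985, and 0 of the 12 genes passed the interaction test by limma. The count of 1 list was 2 without any 1 of libraries 4, 18, 27, 38, 44, 46, 58, 67, 72, 74, 83, 87, 88 and 93, 3 without 43, 51 or 64, and 4 without 94. No explanation was tested for it.

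The regional split called more genes than any of the other divisions of the libraries that were drawn. In wild-type the real split called 3377 genes against 2378 at most in the others, and 1 of 100 splits, the real one, gave as many. In Foxp2hum/hum it called 3550 against 2495, again 1 of 100. Chance alone is argued against for both, though 100 splits cannot give a share below 1 of 100. For genotype chance cannot be excluded: the genes at an unadjusted p under 0.05 numbered 700 in DMS (highest other 3597), 843 in DLS (6474), 321 for the interaction (5658) and 1679 averaged over regions (6100). As many were reached in 32 of 100 splits in DMS, 32 in DLS, 100 for the interaction and 8 for the average. For the interaction the real count was thus at the low end, with a median of 653 in the other splits. If the regions share animals, the interaction p-values may be too large. How often a true interaction would be recovered was not simulated. Splits that call several times the real count point to a structure among the libraries that the groups do not follow.

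Ttr and Ccdc153, markers of choroid plexus and ependyma, were higher in DMS, which borders the lateral ventricle, so tissue from the ventricle wall may contribute to the regional differences. Choroid plexus alone is argued against as the whole cause, since 2597 of the 3377 wild-type calls were kept with Ttr as a covariate, and 2162 of 3550 in Foxp2hum/hum. With Ccdc153 added 219 were kept (307 in Foxp2hum/hum), as the median log2 of the 3377 genes went from 0.54 to 0.39 and their median SE from 0.125 to 0.326, but region explains 95.66% of the variance of Ccdc153 in wild-type and 85.75% in Foxp2hum/hum, so ependymal cells and region cannot be told apart. A lower share of medium spiny neurons in DMS should raise the markers of the other cell types alike. The lowest of 4 medians was -0.0908 (astrocyte) and the oligodendrocyte median 0.14, with members going both ways. Across the calls such a lower share therefore cannot be told apart from region either. In wild-type the 3 dorsolateral gradient genes had a median log2 of -1.63, against -0.37 for the 16 shared medium spiny neuron genes. In Foxp2hum/hum these medians were -1.52 and -0.38. The values argue against a lower share of these neurons as the whole cause for those 3 genes. For the other calls a biological difference between the regions stays open.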

How the results depend on the processing

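Among these settings, the surrogate variables, the covariates from the levels of marker genes (Ttr and Ccdc153 among them), the leave-one-out fits and the fit without libraries 70 and 72 were chosen after seeing the data. The count of genes by genotype in DMS, by interaction and by genotype averaged over regions was 0 under every setting run, and in DLS it was 0 except for DESeq2 (3), array weights (1) and 1 of the leave-one-out fits (range 0 to 1, library 77). Regional counts stayed within 1.5 times the values of 3377 and 3550 for the settings chosen beforehand, and ran from 3079 to 3558 in wild-type and from 3275 to 3656 in Foxp2hum/hum when 1 library was left out. With 1, 2, 3, 5 and 8 surrogate variables the wild-type count was 5630, 5694, 5857, 5370 and 5184, and with 1, 2, 3 and 5 the Foxp2hum/hum count was 5859, 5873, 5994 and 6167. With Ttr and Ccdc153 as covariates the counts were 258 and 348, and with Ttr alone 2279 in Foxp2hum/hum. The lists called by camera fell with an estimated correlation from 7 to 0 (DMS), 10 to 0 (DLS), 13 to 5 (regions, wild-type), 15 to 5 (regions, Foxp2hum/hum), 1 to 0 (interaction) and 13 to 0 (average). Fry gave 0 (DMS), 1 (DLS), 18 (regions, wild-type), 17 (regions, Foxp2hum/hum), 0 (interaction) and 1 (average) lists, and its mixed test 0, 0, 15, 16, 0 and 0. With 5 surrogate variables and an estimated correlation the counts were 0, 1, 7, 7, 0 and 0 in the same order of 6, and by fry 0, 1, 23, 25, 0 and 0. A mean of at least 50 gave 2 lists for the interaction, as did leaving out libraries 70 and 72. Leave-one-out ranges of lists were 6 to 15 (DMS), 7 to 15 (DLS), 11 to 14 and 13 to 16 (regions), 1 to 4 (interaction) and 11 to 16 (average). Named genes were followed as 75 pairs of a gene and a contrast, without the interaction, so a gene named in several contrasts counts more than once. The pairs held Foxp2 and the genes with the smallest p, while the named list members were not followed. Apart from Foxp2, limma adjusted p in the main fit was at most 1.79e-17 between regions and at least 0.344 between genotypes. Most pairs thus lay far from the threshold, and keeping their side of it says little about the other calls. Of the comparisons with alternatives, 1384 kept direction and side of the threshold, and 2 lost the threshold (Foxp2 between regions in Foxp2hum/hum). Another 9 gained it (Foxp2 between regions in wild-type 7 times, Myo3b in DLS 2 times) and 16 changed sign. Foxp2 accounted for 15 of the last: in DMS -0.0027 with edgeR, -0.0051 with DESeq2, -0.041 with array weights and -0.039 with Ttr; in DLS 0.0052, 0.0101, 0.00056 and 0.0021 with 1, 2, 3 and 5 surrogate variables and 0.0157 with Ttr and Ccdc153; averaged, 0.0376, 0.0431, 0.0337, 0.0077 and 0.0059 with 1, 2, 3, 5 and 8 and 0.0092 with Ttr and Ccdc153. Ccdc153 in wild-type was -3.55e-15 when it was its own covariate, by construction. For the others the cause was not tested. Surrogate variables at the default number of 9 could not be fitted. Flow cell, animal block and planned leave-outs of small groups were not run, because the table names no flow cell or animal and every group has more than 10 libraries. No paired analysis was possible because library numbers do not tie libraries to animals. In simulated data the genotype tests recovered 28 of 50 1.5-fold changes in DMS and 24 of 50 in DLS. The simulated genes were independent, so recovery in the real libraries may differ.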

Other observations

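All tests of explanations in this part were chosen only after the result was seen. Several groups had members that differed between regions in wild-type without a call by camera, though some were called by fry. GABA genes lower in wild-type DMS included Gabra4 (log2 -0.58), Gad1 (-0.43) and Gabbr1 (-0.36), and Gabra5 (0.77) was higher, though Gm9962 overlaps Gabra5 with 52.96% of its value (camera adjusted p = 0.304, fry adjusted p = 0.315, fry mixed adjusted p = 0.00157). The dopamine list also went both ways, with Drd2 (-0.64), Drd1a (-0.35) and the vesicular monoamine transporter gene Slc18a2 (-0.46) lower and the D3 receptor gene Drd3 (1.51) higher (camera adjusted p = 0.119, fry adjusted p = 0.00132). Among matrix genes, Gda (1.17), Id4 (1.34, with A330033J07Rik overlapping at 46.35%) and Calb1 (0.27) were higher and Rasgrp2 (-0.80, with Gm14965 overlapping at 25.98%) was lower (camera adjusted p = 0.119, fry adjusted p = 0.000843). In the striosome list Pdyn (1.31) and Lypd1 (0.50, with Gpr39 overlapping at 92.3%) were higher and Kremen1 (-1.07) was lower (camera adjusted p = 0.0983, fry adjusted p = 3.87e-07).

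Published FOXP2 targets and partners included 3 genes higher in wild-type DMS, Mef2c (log2 0.55), Efnb3 (0.22) and Slit1, an axon guidance gene, and 0 lower, with camera adjusted p = 0.0983 and fry adjusted p = 0.0288. Between genotypes 0 of these 11 genes passed in limma in either region (camera adjusted p = 0.333 in DMS and 0.223 in DLS). Among astrocyte genes Gfap (0.92, where the overlapping AL731670.1 has 569.3% of its value) and Gja1 (0.43) were higher and S100b (-0.78, with Dip2a overlapping at 113.5%) and Aldoc (-0.22) lower in wild-type DMS (camera adjusted p = 0.495). Microglia, endothelial and mural, red blood cell and heat shock lists had 0 members passing in wild-type by limma (camera adjusted p = 0.833, 0.833, 0.67 and 0.833). Direct-pathway genes had 1 higher member, Pdyn, and 4 lower, among them Drd1a and the muscarinic receptor gene Chrm4 (-0.67, with Mdk overlapping at 18.08%), with camera adjusted p = 0.12 and fry adjusted p = 0.0827 (mixed 2.08e-08). Among neuropeptide genes Pdyn, Cartpt and Nts were higher and Trh (-0.87) was lower (camera adjusted p = 0.119, fry adjusted p = 0.00954). The septum, oligodendrocyte precursor and glutamatergic neuron lists had camera adjusted p = 0.208, 0.155 and 0.827 in wild-type. The median differed in sign from the mean or the test only in lists that camera did not call, such as the interneuron list in wild-type (median log2 0.04, mean -0.14).

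Libraries 70 (wild-type DLS) and 72 (wild-type DMS) held 98 features with a median ratio of 16.23 to the median of the libraries. Of 10 short features, 100% matched another of the features, against 10% of length-matched others, so a repeated sequence shared by them may account for it. RNA without a poly(A) tail carried into these libraries is a candidate source too, since summed copies of the 7SK RNA stood 11.68 and 24.36 times above the median of the others. Depth is argued against, at 24.89 and 18.86 M reads, inside the range of the other libraries. No biological explanation was tested.

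A cluster of 75 genes on chromosome 2 (174469035 to 178073197) was found in the data to have 62 genes on the higher side in Foxp2hum/hum, with a mean log2 of 0.17 (permutation p = 0.0228) and 0 genes passing by limma. Its bounds were chosen by looking at the values, and the p does not allow for that choice or for the other places that could have been chosen.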
